A study of Homo sapiens with 8 samples.

How the data were processed

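Total RNA of SW620 cells was converted to biotin-labelled cRNA from inputs of 250 to 500 ng and hybridised to Illumina bead arrays, 1 array per sample, per the labels' protocols. The 8 samples were grouped by their titles into untreated, Y15, HAS3 siRNA and scrambled, with 2 arrays each. The deposited non-normalized table holds the bead-summary intensity of each of 24526 probes on a linear scale, and per the file headers a detection p-value beside each intensity. GenomeStudio is named in the submitters' processing notes, and its version and settings are not given in the sources used here. The table held no value below 0 and its lowest value on each array was between 25.4 and 29.7, so no background had been subtracted. The deposited series matrix holds log2 values of the same arrays, whose scale was found by comparison: they equal the log2 of the non-normalized intensities after quantile normalization with no background correction, to within 5e-09, and their median was 5.86 on each array. No centring of genes was found.

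Detection p-values were matched to their arrays by their place beside each intensity column. Each was checked to fall with rising intensity. Background was corrected with limma's nec function, which takes the background from the detection p-values where no negative control probes are listed (offset 16), followed by quantile normalization between arrays and log2. Probes with a detection p-value under 0.05 on at least 2 of the 8 arrays were kept, 14631 in all. Gene symbols came from the platform annotation, updated through gene identifiers with a current RefSeq gene list (assembly GRCh38.p14), which was used for names only. Of all probes 21834 probes had 1 symbol (21813 of them found in that list and 21 left with the platform's symbol), none had several, and 2692 were not listed with a gene and stay unnamed here. Of the kept probes 13239 were named. The probe of highest mean log2 intensity stood for each gene, which gave 10856 genes, of which 1793 had more than 1 probe. Where a gene called with Y15 had another kept probe, 81.5% of 1138 such probes moved in the same direction, against 91.1% of 191 with HAS3 siRNA; among genes named by the rule below, a second probe of PTK2, RPL13 and P4HA1 passed in the opposite direction to the probe used with Y15, and that of P4HA1 also between the control groups. HAS1 had no named probe among those used and was not analysed here.

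A linear model with 4 group means was fitted to all 8 arrays with lmFit and eBayes of limma, so that all groups share 1 estimate of spread (4 residual and 11.8 total degrees of freedom). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 10856 genes of a comparison. The comparisons were Y15 minus untreated, HAS3 siRNA minus scrambled, their difference, and scrambled minus untreated. HAS3 siRNA minus untreated was added after the results were seen. In each, n is 2 arrays per group. All adjusted p-values of single genes are from limma, and tests are two-sided. Where a gene was undetected on both arrays of the dimmer group, the fold is a lower bound, "at least", computed from the mean normalized log2 level of the brighter group against, on each array of the dimmer group, the higher of the gene's own level and the lowest level among detected probes. In all, 33 lists of genes were drawn up from general knowledge, covering signalling targets, stress responses, cell division, metabolism, adhesion and hyaluronan, differentiation and markers of other cell types; 32 had at least 5 members tested and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists of a comparison, and again with an estimated correlation and with fry, which tests whether the members of a list move one way on balance. The counts of lists include 1 called list that is not reported here. Overlaps of called genes were compared with independent lists by two-sided Fisher exact tests, adjusted over 4 overlaps. Because both comparisons use the same spread of each gene, the overlaps were also set against independent lists within 20 bins of genes of like standard error, by exact Mantel-Haenszel tests.

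The genes named were chosen by a rule: HAS3 and PTK2 always, and HAS2, CD44 and HMMR; in each comparison the 12 largest rises and 12 largest falls among genes past the threshold with both arrays of 1 group on the same side of both of the other; up to 4 members of smallest p of each list; of genes changed in both comparisons the 10 with the largest smaller change; and the 5 largest differences between effects. Placeholder symbols were passed over. The groups, tests, gene lists, this rule and the alternative settings were fixed before the data were examined. The alternatives were no background correction, normexp with offset 50, median centring, cyclic loess, the series matrix values, no detection filter, detection p under 0.01 on all 8 arrays, all probes, the mean of probes, a fit of the 4 arrays of a comparison alone, the replicate number as a block, eBayes with trend and robust, 2 other thresholds, other list tests and leaving out each array in turn.

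The procedure was tested on simulated data with the mean level of each real gene and a spread drawn from the fitted distribution of gene variances, 2 arrays per group and 10856 genes. In the simulation of Y15 against untreated it recovered 78% of 100 genes changed 2-fold and 19% of 100 changed 1.5-fold, and in that of HAS3 siRNA against scrambled 85% and 29%. Changes of 1.5-fold were therefore mostly missed in the simulations. These changed far fewer genes than the 4538 and 892 that passed in the real comparisons, so that their adjusted threshold was stricter. The share of 1.5-fold changes missed in the real data was not measured. Array precision cannot be given as a depth, and the array number limits it. The tools were R 4.3.3, limma 3.58.1, version 1.17.8 of data.table and matplotlib 3.10.9.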

Results

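SW620 is an established human colorectal cancer cell line. Gene expression was profiled on 8 single-colour Illumina bead arrays, 2 for each of 4 groups of SW620 cells kept for 24 h: untreated cells, cells given 4 uM Y15, cells transfected with an siRNA against HAS3, and cells transfected with a scrambled sequence. Y15 is a small-molecule inhibitor of focal adhesion kinase (FAK), the integrin-associated kinase encoded by PTK2. HAS3 is one of the synthases that make hyaluronan, a polysaccharide of the extracellular matrix. The design set Y15 against untreated cells and HAS3 siRNA against the scrambled sequence, and the study asked which genes respond to both inhibitions. Mean probe intensity per array lay between 352.1 and 524.7, except on the second Y15 array, where it was 234.1. Detection reached 12578 to 13916 of 24526 probes per array. Across genes, which are not independent replicates, arrays of one group correlated at r = 0.9899 to 0.9956 and arrays of different groups at r = 0.9478 to 0.9864. The number of arrays limits the precision of every value here. Nothing states that replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

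The first check was the transcript of the silenced gene. HAS3 had a mean log2 intensity of 9.89 ± 0.23 (SD, n = 2) in the HAS3 siRNA arrays and 10.32 ± 0.23 (SD, n = 2) in the scrambled arrays. This is a 1.35-fold lower level, with a log2 fold change of -0.43 ± 0.17 (SE) and a 95% interval of -0.80 to -0.07, and it did not pass adjustment over all genes (limma adjusted p = 0.151). Both siRNA arrays lay below both scrambled arrays, and a second, dimmer HAS3 probe also read lower, at 6.64 ± 0.20 against 6.95 ± 0.21 (SD, n = 2). In untreated cells HAS3 stood at 9.41 ± 0.12 (SD, n = 2), so that it was 1.88-fold higher in scrambled than in untreated cells (adjusted p = 0.00329, and 0.0517 without the first scrambled array). In a comparison added after the results were seen, the HAS3 siRNA arrays read 0.48 ± 0.17 (SE) above untreated cells on the log2 scale (adjusted p = 0.0534). Y15 left HAS3 at 9.33 ± 0.16 (SD, n = 2; adjusted p = 0.742).

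The other genes of the FAK and hyaluronan system moved in several directions. PTK2, the FAK gene, had a log2 fold change of -0.11 ± 0.14 (SE) with Y15 (adjusted p = 0.586) and of -0.12 ± 0.14 with HAS3 siRNA (adjusted p = 0.687), while a much dimmer second PTK2 probe rose by 0.55 on the log2 scale with Y15. HAS2, another hyaluronan synthase, rose 1.48-fold with Y15 (adjusted p = 0.00498) and 1.56-fold with HAS3 siRNA (adjusted p = 0.0107). The HAS2 call with HAS3 siRNA was lost when any 1 of the 4 arrays of that comparison was left out, with adjusted p between 0.069 and 0.0985. CD44, the main cell-surface hyaluronan receptor, rose 2.28-fold with Y15 and was 2.54-fold higher in scrambled than in untreated cells, and it had a log2 fold change of -0.26 ± 0.15 (SE) between HAS3 siRNA and scrambled (adjusted p = 0.353). A second, dimmer CD44 probe read 0.41 higher with Y15 and 0.69 higher in scrambled than in untreated cells on the log2 scale, and passed in neither. HMMR, a hyaluronan-binding mitotic protein, fell 2.07-fold with Y15 and had a log2 fold change of -0.15 ± 0.16 (SE) with HAS3 siRNA (adjusted p = 0.631).

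**Figure D1:**
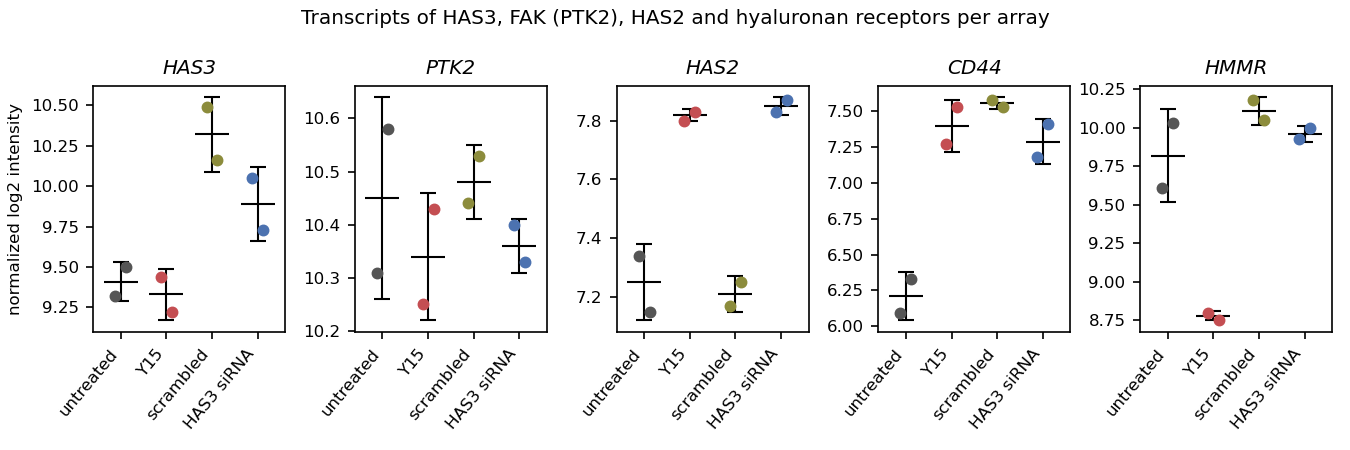
Normalized log2 intensity of HAS3, PTK2, HAS2, CD44 and HMMR (y axis, a separate scale for each gene) on each array of the 4 groups (x axis). Points are arrays and black bars the mean ± SD of 2 arrays; HAS3 was highest in the scrambled group (10.32 ± 0.23), and HMMR lowest in the Y15 group (8.78 ± 0.03).

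Y15 raised a set of surface, signalling and growth-control genes by more than 10-fold, as read by the probe used for each. CD55, a complement inhibitor on the cell surface, rose 48-fold (log2 fold change 5.58 ± 0.16, SE, n = 2 arrays per group), the membrane protein gene EMP1 rose 25.6-fold, and DUSP5, a phosphatase that inactivates ERK, rose 24.9-fold. The transcription cofactor LBH rose 17.1-fold, the kinase PIM1 13.3-fold, RAET1L, a ligand of the NKG2D receptor of immune cells, 11.7-fold, and the scaffold AKAP12, the secreted FGF carrier FGFBP1 and the cell-cycle regulator RGCC 10.1-fold each. Second probes of LBH and AKAP12 also passed but rose less. Their log2 fold changes were 1.64 and 2.33, against 4.09 and 3.34 by the probes used. Members of near-identical gene groups also rose, so that the exact gene is uncertain: the chorionic gonadotropin genes CGB5 (at least 16.5-fold) and CGB1 (at least 10.6-fold), and the glucose transporter SLC2A3 (11-fold), which closely resembles SLC2A14. The largest falls were smaller, from 7.03-fold for PSD2 to 4.34-fold for TCEA3. Between them lay PPP2R2C, a regulatory subunit of phosphatase 2A (5.81-fold), complement component C5 (5.62-fold), TSPAN32 (5.42-fold) and the globin gene HBQ1 (5.31-fold). They also included SPAG16 (4.94-fold), the kisspeptin receptor KISS1R (4.72-fold), LFNG, which modifies Notch receptors (4.70-fold), the NADPH oxidase activator NOXA1 (4.69-fold), the stem cell marker SMOC2 (4.99-fold) and CDX2, the intestinal master transcription factor (4.40-fold). Second probes of TSPAN32 and LFNG passed with smaller log2 fold changes, -0.80 and -1.13, against -2.44 and -2.23 by the probes used. That of PPP2R2C read -2.85, against -2.54. Each of these 24 genes had both Y15 arrays on one side of both untreated arrays, at limma adjusted p of 3.59e-06 or less. PSD2 and SPAG16 were detected on only 1 of the 2 Y15 arrays, so background limits the size of the falls that could be read.

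Genes that answer growth factors and inflammatory signals rose together with Y15. Of 34 immediate early genes measured, 19 rose and 1 fell (21 and 1 adjusted over the list alone), among them FOSL1, a subunit of the AP-1 transcription factor (7.03-fold) and ZFP36, which destabilises inflammatory mRNAs (4.11-fold). The immediate early list passed camera at adjusted p = 1.34e-06, and had adjusted p = 0.251 with an estimated correlation. The list of NF-kB targets and inflammatory cytokines had 27 members on the array, of which 12 passed the detection filter. That filter asks for 2 arrays, so it also keeps a gene detected only with Y15. Of these 12, 10 rose and none fell, the same counts adjusted over the list alone, including the chemokine CXCL8 (4.96-fold), the NF-kB inhibitor TNFAIP3 (4.85-fold) and RELB (3.24-fold). These NF-kB targets had adjusted p = 5.16e-05, and adjusted p = 0.21 with an estimated correlation. YAP and TEAD targets had 9 rises and 2 falls among 16 (9 and 3 adjusted over the list alone), led by the matricellular genes CCN2 (5.60-fold) and CCN1 (3.25-fold) and the receptor kinase AXL (3.40-fold). The YAP and TEAD list had adjusted p = 0.00461, and adjusted p = 0.21 with an estimated correlation. Of 26 mesenchymal and TGF-beta genes, 12 rose and 6 fell (12 and 7 adjusted over the list alone), with the transcriptional repressor SNAI2 up 9.57-fold, the urokinase receptor PLAUR up 7.23-fold and urokinase itself, PLAU, up 3.33-fold. For the mesenchymal list camera gave adjusted p = 0.0422, and adjusted p = 0.303 with an estimated correlation.

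Several groups of stress response genes also rose with Y15. Among 22 heat shock genes 13 rose and none fell, the same counts adjusted over the list alone, with the co-chaperone BAG3 up 5.58-fold, DNAJB1 up 2.58-fold, and HSPA1B and HSPA1A, near-identical copies that the probes may not tell apart, up 6.69-fold and 5.53-fold. The heat shock list had adjusted p = 1.46e-05, and adjusted p = 0.21 with an estimated correlation. Of 27 NRF2 targets, which defend against oxidants, 14 rose and none fell (14 and 1 adjusted over the list alone), including SRXN1 (3.16-fold) and TXNRD1 (2.70-fold). As a list the NRF2 targets had adjusted p = 7.32e-05, and adjusted p = 0.21 with an estimated correlation. The metal-binding metallothioneins and their zinc-responsive companion SLC30A1 had 6 rises and no fall among 7, the same counts adjusted over the list alone, with MT1H up 2.60-fold (adjusted p = 0.00194, and adjusted p = 0.21 with an estimated correlation). Proteasome subunits had 15 rises and 1 fall among 27 (17 and 1 adjusted over the list alone), PSMD12 leading at 2.36-fold (adjusted p = 0.000204, and adjusted p = 0.234 with an estimated correlation). Targets of ATF4, the transcription factor of amino acid shortage, went both ways, with 8 rises and 7 falls among 41 (7 and 6 adjusted over the list alone; camera adjusted p = 0.783). The phosphatase regulator PPP1R15A rose 4.6-fold and CBS, an enzyme of cysteine synthesis, fell 3.69-fold. Chaperones of the endoplasmic reticulum and other genes of the unfolded protein response had 9 rises and 2 falls among 24. This list did not pass either (camera adjusted p = 0.0903).

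Wnt targets and colon stem cell markers were the group that fell with Y15. Of 22 measured, 14 fell and 3 rose, the same counts adjusted over the list alone, with SMOC2 down 4.99-fold, the stem cell transcription factor ASCL2 down 3.81-fold and SP5 down 3.22-fold, while the Wnt antagonist DKK1 rose at least 3.81-fold. The Wnt list had adjusted p = 0.00381, and adjusted p = 0.25 with an estimated correlation. Among 47 G1/S and E2F targets 11 rose and 4 fell (11 and 1 adjusted over the list alone), with the phosphatase CDC25A up 2.67-fold and the exonuclease EXO1 up 2.04-fold (adjusted p = 0.0422, and adjusted p = 0.223 with an estimated correlation). Of 51 genes of G2/M and mitosis, 16 fell and 5 rose, the same counts adjusted over the list alone, including the kinetochore genes CENPF and CENPA, each 2.15-fold lower, but the list itself did not pass (adjusted p = 0.0861). Focal adhesion genes divided evenly, 13 up and 13 down among 46, also adjusted over the list alone (adjusted p = 0.465). The caveolin gene CAV1 rose 2.86-fold, and CAV2 rose 2.86-fold by the probe used, while its second, dimmer probe had a log2 fold change of -0.24 and did not pass. The adhesion and actin regulators TNS3 and ENAH fell 3.33-fold and 2.67-fold. Hyaluronan genes had 3 rises and 4 falls among 14, the same adjusted over the list alone (adjusted p = 0.866), with UGDH, which makes a hyaluronan precursor, up 2-fold and CEMIP, a hyaluronan-degrading protein, down 1.89-fold.

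In all, 2040 of 10856 genes were higher and 2498 lower with Y15 at an adjusted p under 0.05, or 41.8% of the genes tested, and 487 rose and 575 fell at least 2-fold. The 2 groups did not overlap at 67.8% of genes, where chance gives 33.3%. None of the 11 list calls held with an estimated correlation, those for the G1/S and mesenchymal lists were also lost under several other settings, and with the stricter detection filter the YAP and TEAD call was lost and the NF-kB list had too few members left to be tested. Correlation among members does not alone account for the first of these losses. For NRF2 targets the estimated correlation, 0.005, was below the preset 0.01, yet the unadjusted camera p rose from 9.15e-06 to 0.00922. Among the genes called, 45.0% were higher, but 64.9% (2859 higher, 1548 lower) when arrays were centred on their medians instead of quantile normalized, a setting that moved the median change of all genes from -0.03 to 0.22 on the log2 scale.

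**Figure D2:**
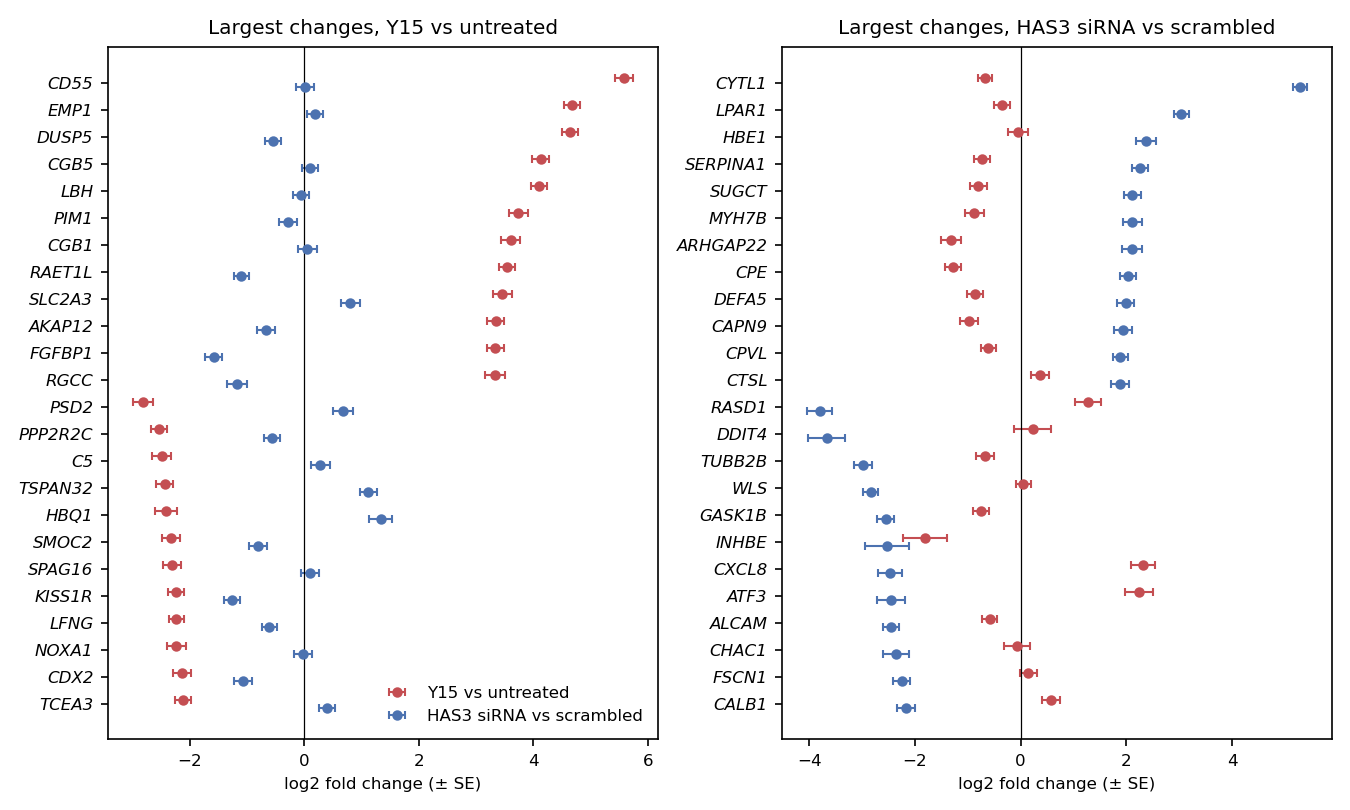
Fitted log2 fold changes (x axis, points ± SE) of the 12 largest rises and 12 largest falls (y axis) with Y15 (left) and with HAS3 siRNA (right), each gene shown in both comparisons in red and blue; every group has 2 arrays. CD55 rose by 5.58 with Y15, and CYTL1, plotted at its fitted value although undetected in the scrambled arrays, had 5.29 with HAS3 siRNA; CXCL8 and ATF3 lay on opposite sides of 0 in the 2 comparisons.

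Compared with scrambled cells, the largest falls in cells given HAS3 siRNA were those of RASD1, DDIT4, TUBB2B and WLS. RASD1, a Ras-related GTPase, fell 14-fold (log2 fold change -3.80 ± 0.24, SE, n = 2 arrays per group), DDIT4, an mTORC1 inhibitor, fell 12.7-fold, the tubulin gene TUBB2B 7.88-fold, and WLS, which carries Wnt proteins to the cell surface, 7.14-fold. Further falls were GASK1B (5.88-fold), the inhibin subunit INHBE (5.77-fold), CXCL8 (5.52-fold), the stress transcription factor ATF3 (5.50-fold) and the adhesion molecule ALCAM (5.47-fold). Also lower were the glutathione-degrading enzyme CHAC1 (5.10-fold), the actin-bundling protein FSCN1 (4.76-fold) and the calcium-binding protein CALB1 (4.49-fold). Other probes of WLS passed with log2 fold changes between -1.84 and -1.25, against -2.84 by the probe used. The second probe of GASK1B read -2.44, against -2.56. The scrambled arrays differed in several of these falling genes. On the log2 scale they read 7.66 and 8.73 for ATF3, 8.50 and 9.40 for RASD1, 7.42 and 8.32 for CHAC1, and 9.92 and 10.65 for CXCL8. They differed most in DDIT4 (10.88 and 12.42) and INHBE (7.03 and 8.86) among these. Without the second scrambled array DDIT4 fell by 2.90 instead of 3.67 on the log2 scale and INHBE by 1.62 instead of 2.53, and without the first by 4.44 and 3.44. INHBE lost its call without the first HAS3 siRNA array (adjusted p = 0.0582). The largest rises were CYTL1, a secreted cytokine-like protein (at least 28.5-fold), LPAR1, a receptor for lysophosphatidic acid (at least 6.13-fold), the globin gene HBE1 (5.19-fold) and the protease inhibitor SERPINA1 (4.78-fold). They were followed by SUGCT and MYH7B (4.33-fold each), ARHGAP22 (4.31-fold), the prohormone-processing enzyme CPE (4.10-fold), CPVL (3.70-fold), the lysosomal protease CTSL (3.69-fold), CAPN9 (at least 3.49-fold) and the intestinal defensin DEFA5 (at least 3.06-fold). In each of these rises scrambled cells lay below untreated cells. HBE1, for example, had mean log2 levels of 7.61 in untreated, 5.79 in scrambled and 8.17 in HAS3 siRNA cells. The falls went both ways: scrambled stood above untreated for GASK1B (7.64 against 5.57) and below it for FSCN1 (12.25 against 12.41).

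Among targets of ATF4, the regulator of the integrated stress response, many were lower after HAS3 siRNA, although the members of this list were strongly correlated (estimated correlation 0.602). Of 41 measured, 17 fell and none rose (22 and 0 adjusted over the list alone), with a median log2 fold change of -0.59. Besides DDIT4, CHAC1 and ATF3, CBS fell 2.51-fold (camera adjusted p = 5.26e-13, and adjusted p = 0.647 with an estimated correlation). With fry it did not pass (adjusted p = 0.127). The 2 scrambled arrays differed from each other in this group. Relative to untreated cells its median log2 level was -1.03 in the first and -0.45 in the second, against -1.31 and -1.37 in the HAS3 siRNA arrays. Without the second scrambled array the median change was -0.36 (adjusted p = 1.38e-08). Immediate early genes had 9 falls and 2 rises among 34 (13 and 3 adjusted over the list alone), with KLF4, an epithelial transcription factor, down 3.06-fold, NR4A2 down 1.92-fold and KLF2 up 2.13-fold. Immediate early genes as a list had adjusted p = 0.00292, and adjusted p = 0.647 with an estimated correlation. Genes of intestinal epithelial differentiation had 6 falls and 1 rise among 14 (6 and 2 adjusted over the list alone), including the mucin MUC13 (3.20-fold), the adhesion molecule CEACAM6 (3.01-fold) and the transcription factor KLF5 (2.14-fold). The differentiation list had adjusted p = 0.012, adjusted p = 0.0195 with fry, and adjusted p = 0.647 with an estimated correlation. The median of this list, -0.20, was -0.12 without the first HAS3 siRNA array.

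Cholesterol synthesis genes were the group with the clearest rise after HAS3 siRNA. Of 17 measured, 5 rose and none fell (7 and 0 adjusted over the list alone), with NSDHL up 2.51-fold and the rate-setting squalene epoxidase SQLE up 2.07-fold. The cholesterol list had adjusted p = 0.000425, and adjusted p = 0.339 with an estimated correlation. Wnt targets and colon stem cell markers had 5 rises and 2 falls among 22 (7 and 2 adjusted over the list alone), with the Wnt inhibitor APCDD1 up 2.58-fold, the receptor kinase EPHB3 up 2.18-fold, the transcription factor LEF1 up 2.17-fold and AMACR down 1.97-fold. For this Wnt list camera gave adjusted p = 0.0361, and adjusted p = 0.647 with an estimated correlation. MYC targets and ribosome biogenesis genes passed as a list at a median of 0.17. DKC1, at 1.60-fold, was the single member of 38 to pass, also adjusted over the list alone (adjusted p = 0.0159, and adjusted p = 0.384 with an estimated correlation). Focal adhesion genes had 5 falls and no rise among 46 (6 and 0 adjusted over the list alone; camera adjusted p = 0.278), among them the actin regulator ENAH (1.98-fold), whose second probe also fell. The docking protein NEDD9 (3.11-fold) and the actin regulators ZYX (1.54-fold) and TES (1.52-fold) fell by the probe used, but their other probes had log2 fold changes between -0.21 and 0 and did not pass. Of 14 hyaluronan genes HAS2 rose and CEMIP fell 1.98-fold, and the other 12 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.882). The adherens junction gene CDH1, which encodes E-cadherin, fell 3.49-fold within an epithelial junction and keratin list that had 3 falls and no rise among 27 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0594).

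HAS3 siRNA thus gave 377 genes higher and 515 lower than scrambled at an adjusted p under 0.05, or 8.22% of the genes tested, and 83 rose and 117 fell at least 2-fold. The 2 groups did not overlap at 57.6% of genes, where chance gives 33.3%. The counts were lower when either HAS3 siRNA array or either scrambled array was left out, at 153 to 179 genes higher and 164 to 273 lower, and with median centring, at 164 higher and 298 lower. None of the 6 list calls held with an estimated correlation, and further settings ended some of them: the stricter detection filter and leaving out the second array of either group (Wnt list), all probes (Wnt and MYC lists), leaving out the first HAS3 siRNA array (MYC list), no detection filter (differentiation list) and fry (ATF4, immediate early and Wnt lists). The cholesterol list had an estimated correlation of -0.027, below the preset 0.01, yet its unadjusted camera p rose from 2.65e-05 to 0.0106. Correlation among members therefore does not alone account for its lost call.

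**Figure D3:**
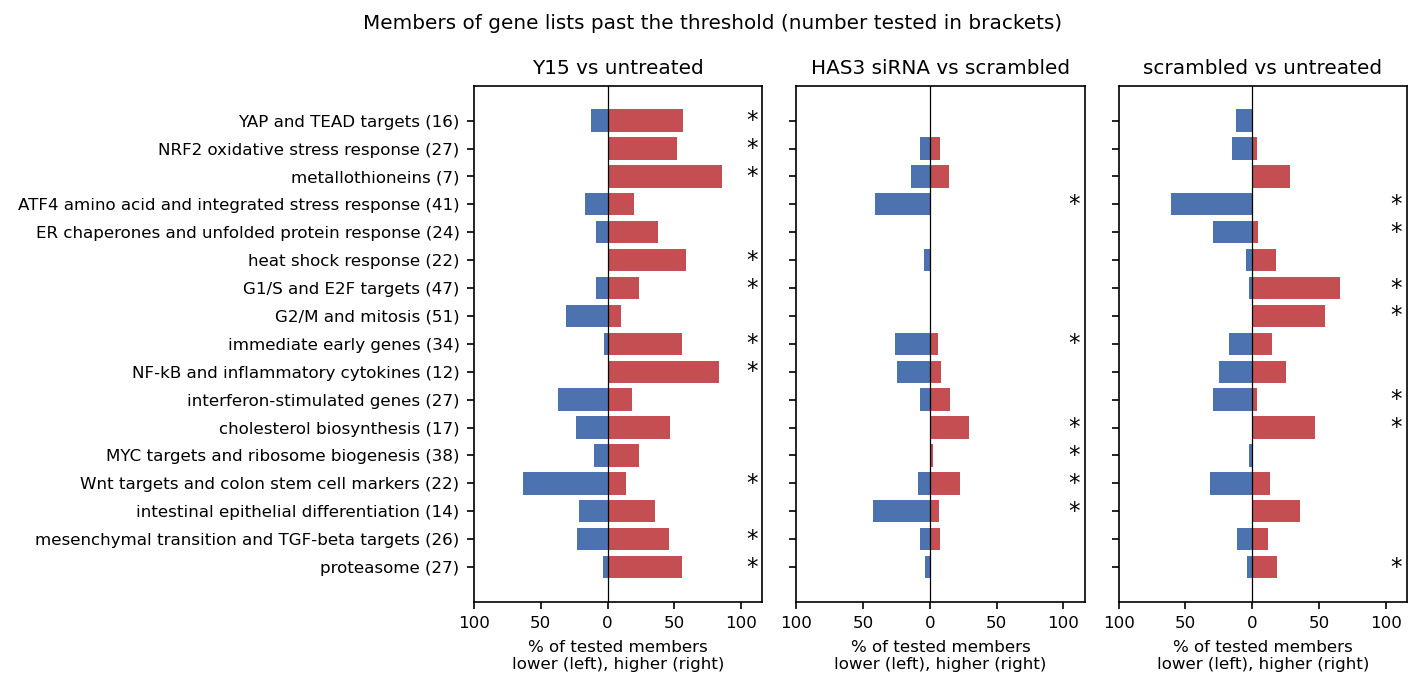
Percent of the tested members of each gene list (y axis, number tested in brackets) that were higher (red, to the right) or lower (blue, to the left) past the threshold in 3 comparisons of 2 arrays against 2. Asterisks mark lists with a camera adjusted p under 0.05 at a preset correlation; 10 of 12 NF-kB genes rose with Y15, and 17 of 41 ATF4 targets fell with HAS3 siRNA.

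The genes shared by both comparisons were next examined, which is the question of the study. Of the 10 genes with the largest changes in both comparisons, 7 rose with Y15 and fell with HAS3 siRNA. Among these were CXCL8 (4.96-fold up, 5.52-fold down), ATF3 (4.72-fold up, 5.50-fold down) and the growth factor HBEGF (5.09-fold up, 3.55-fold down). The others were FGFBP1 (10.1-fold up, 2.98-fold down), CEACAM6 (3.46-fold up, 3.01-fold down), the gap junction gene GJB2 (3.10-fold up, 2.85-fold down) and TMEM154 (3.14-fold up, at least 2.27-fold down). For FGFBP1 and CEACAM6 the falls are only relative to scrambled cells (log2 means 8.83 and 7.04). HAS3 siRNA cells (7.26 and 5.45) stood above untreated cells (5.43 and 4.88) in both. For CXCL8, ATF3, HBEGF and GJB2 the HAS3 siRNA mean lay below the untreated mean. INHBE fell 3.51-fold with Y15 and 5.77-fold with HAS3 siRNA, and TMEM176A fell 2.81-fold and 4.04-fold. RGS2, a regulator of G protein signalling, rose 6.96-fold and 2.92-fold, although its untreated arrays differed, at 5.57 and 6.59 on the log2 scale.

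Altogether 490 genes passed in both comparisons, 260 in the same direction and 230 in opposite directions, a same-direction share of 53.1% (exact 95% binomial interval 48.5% to 57.6%, which treats genes as independent). The 2 comparisons share no array, but they share 1 estimate of spread per gene. Genes lower in both numbered 194, where independent lists would give 119 (odds ratio 2.11, two-sided Fisher exact test p = 1.95e-14, adjusted over 4 overlaps 7.8e-14). Within 20 bins of genes of like standard error, a test added after the results were seen, independent lists would give 122 (common odds ratio 2.04, exact adjusted p = 9.04e-13). Genes lower with Y15 and higher with HAS3 siRNA numbered 125 against 86.7 (odds ratio 1.69, Fisher exact p = 4.87e-06, adjusted 9.74e-06), and against 88.4 within these bins (exact adjusted p = 2.52e-05). Among the 8738 genes not called between the 2 control groups, this excess was not detected, at 46 against 40.6 (adjusted Fisher exact p = 0.471). Genes lower in both stayed in excess there, at 132 against 64.5 (odds ratio 2.90, adjusted Fisher exact p = 8.56e-18). Those 8738 genes were, however, chosen on the control arrays of both comparisons. Keeping genes of close control levels by itself favours changes in the same direction over opposite ones. Neither the lost nor the remaining excess therefore tells whether the difference between the control groups accounts for it. The 66 genes higher in both (70.8 for independent lists) and the 105 higher with Y15 and lower with HAS3 siRNA (96.8) did not differ detectably from independent lists (adjusted Fisher exact p = 0.546 and 0.473). All these overlap tests likewise treat genes as independent, although related genes were correlated, as ATF4 targets were at an estimated 0.602. Their p-values are therefore smaller than correlated genes would warrant. Across all 10856 genes the 2 sets of log2 fold changes had a Pearson r of -0.0113 and a Spearman rho of -0.00907. Median centring lowered the number of genes lower in both to 81 and gave r = -0.10, but it also called fewer falls, 1548 with Y15 and 298 with HAS3 siRNA. Leaving out any 1 array of the HAS3 siRNA comparison likewise lowered the number lower in both and the number of falls called with HAS3 siRNA. What independent lists would give under these settings was not computed.

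**Figure D4:**
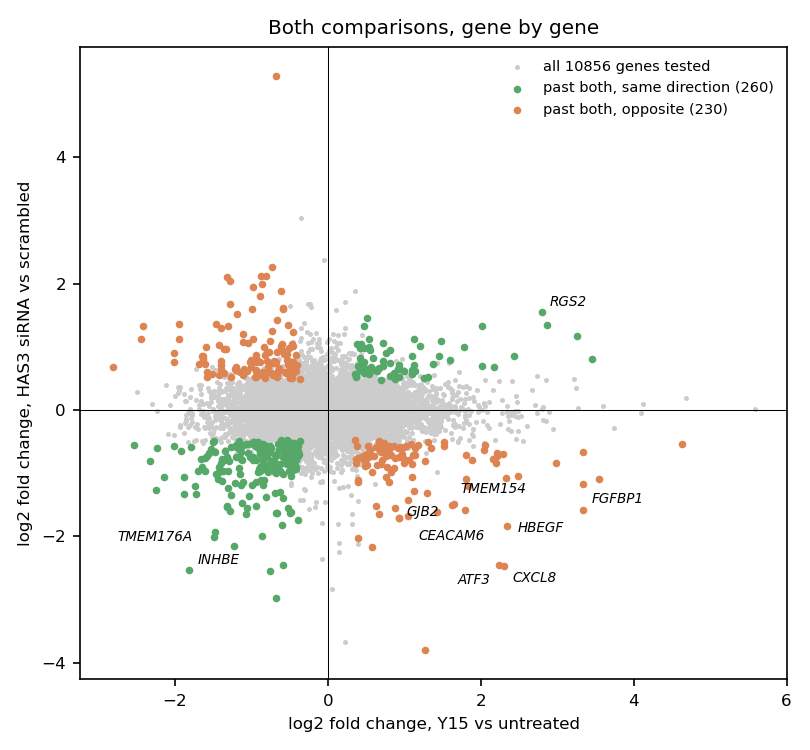
Log2 fold change of each gene with Y15 (x axis) and with HAS3 siRNA (y axis), each from 2 arrays against 2. Grey points are all 10856 genes tested, green points the 260 that passed both comparisons in the same direction and orange points the 230 that passed in opposite directions; the 10 genes with the largest changes in both are named.

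A direct test of the difference between the 2 effects separated the genes whose response to HAS3 siRNA exceeded or fell short of that to Y15. CYTL1 was at least 28.5-fold higher with HAS3 siRNA and fell by 0.68 on the log2 scale with Y15, and no exact difference is given because it was undetected in the scrambled arrays. CD55, which rose 48-fold with Y15, was likewise undetected there, and no exact difference is given for it. Among detected genes DUSP5 (-5.18 ± 0.20, SE, on the log2 scale), RASD1 (-5.08 ± 0.34) and FGFBP1 (-4.91 ± 0.21) changed less upwards or further downwards with HAS3 siRNA than with Y15. By gene list, 1 of 32 differed upwards, the Wnt targets and colon stem cell markers (adjusted p = 0.000541, and adjusted p = 0.233 with an estimated correlation). A downward difference was found for 9 lists, the smallest adjusted p being that of the immediate early genes (2.13e-08, and adjusted p = 0.233 with an estimated correlation). Among the others were NF-kB targets (adjusted p = 7.86e-05), NRF2 targets, heat shock genes and ATF4 targets (adjusted p = 0.000449 each), proteasome subunits (adjusted p = 0.0038), YAP and TEAD targets (adjusted p = 0.0179) and metallothioneins (adjusted p = 0.0301). None of these passed with an estimated correlation: adjusted p = 0.533 with an estimated correlation for ATF4 targets, 0.278 for the proteasome and 0.233 for each of the other 5. In total 1850 genes differed upwards and 1495 downwards, so that 55.3% were upwards, against 30.7% (994 and 2246) with median centring. Without the first scrambled array 1223 differed upwards.

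The 2 control groups differed as well, among others in genes of amino acid supply and cell division. ASS1, which makes the arginine precursor argininosuccinate, was 14.4-fold lower in scrambled than in untreated cells (log2 fold change -3.85 ± 0.15, SE, n = 2 arrays per group), CPE was 8.81-fold lower and CYTL1 at least 6.44-fold lower. FGFBP1 was 10.6-fold higher, RASD1 4.79-fold and CEACAM6 4.47-fold. Of 41 ATF4 targets 25 were lower and none higher (29 and 0 adjusted over the list alone), including asparagine synthetase ASNS (5.39-fold), CBS (4.95-fold) and PHGDH, the entry enzyme of serine synthesis (4.72-fold). Their median was -0.74, and -0.45 without the first scrambled array (adjusted p = 1.56e-11, and adjusted p = 0.54 with an estimated correlation). Of 47 G1/S and E2F targets 31 were higher and 1 lower (37 and 1 adjusted over the list alone), including RRM2 (3.25-fold), which supplies deoxynucleotides, and the replication factors GINS2 (2.50-fold) and MCM4 (2.10-fold). This list passed both at the preset correlation (adjusted p = 2.34e-15) and with an estimated one (adjusted p = 0.0174). Of 51 genes of G2/M and mitosis 28 were higher and none lower (37 and 0 adjusted over the list alone), such as KIF11 (2.03-fold) and CDCA3 (2.05-fold), at adjusted p = 6.6e-15, and adjusted p = 0.177 with an estimated correlation.

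Cholesterol synthesis genes were also higher in scrambled than in untreated cells, 8 of 17 with none lower, also adjusted over the list alone, including SQLE at 1.73-fold (adjusted p = 0.000276, and adjusted p = 0.177 with an estimated correlation). Interferon-stimulated genes were lower, with 8 falls and 1 rise among 27 (9 and 1 adjusted over the list alone), such as ISG20 (2.70-fold), at adjusted p = 0.0307, and adjusted p = 0.414 with an estimated correlation. Their median, -0.30, was -0.17 without the second untreated array, with the call lost. It was -0.13 without the first and -0.18 without the first scrambled array. Proteasome subunits had 5 rises and 1 fall among 27 (6 and 1 adjusted over the list alone), with PSMD11 up 1.62-fold, at adjusted p = 0.0307, and adjusted p = 0.511 with an estimated correlation. Chaperones of the endoplasmic reticulum and other genes of the unfolded protein response had 7 falls and 1 rise among 24 (8 and 1 adjusted over the list alone), with DNAJB9 down 2.34-fold, at adjusted p = 0.0393, and adjusted p = 0.44 with an estimated correlation. The calls of these last 2 lists were also lost with the stricter detection filter and without the second scrambled array. In total 960 genes were higher and 1158 lower, or 19.5% of the genes tested, and 62.9% of genes had no overlap between the groups, where chance gives 33.3%. The share higher was 45.3%, and 56.2% (706 higher, 551 lower) with median centring, which moved the median of all genes from 0.00 to 0.13. The counts fell to 384 and 564 without the first untreated array, to 278 and 418 without the first scrambled array and to 440 and 633 without the second.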

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

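Of the tests in this part, those of an interferon response, of swapped samples and of a separate batch were chosen only after the results were seen. Probes that the annotation lists with no gene were left out of the comparisons, and they carried signal as well: with Y15, 557 of 1392 such probes passed (298 higher, 259 lower; 40.0%, against 40.1% of named probes), the largest log2 fold change being 4.81. With HAS3 siRNA 104 passed (48 higher, 56 lower; 7.47%, against 7.23% of named probes), the largest being -1.99.

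The breadth of the Y15 response was weighed first, because the second Y15 array was dim. If that array alone carried the response, the changes of the first and of the second array, each against its own untreated array, would correlate poorly; across genes they correlated at r = 0.859 (0.768 with the untreated arrays exchanged), which argues against it. Quantile normalization of arrays of unequal brightness was examined with median centring, which kept 94.7% of the rises and 62% of the falls. Since this setting moved the changes of all genes upwards together, it favours rises by construction, and the effect of normalization on the numbers of rises and falls stays open. A response of the cells to Y15 stays open as well, and these arrays cannot tell FAK inhibition from other actions of the compound.

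The genes that differ between HAS3 siRNA and scrambled cells were weighed next, since HAS3 itself did not pass. If they came from the scrambled sequence, the HAS3 siRNA arrays would mostly lie closer to untreated cells than the scrambled arrays do, but this was so for 34.1% of the genes called (exact 95% interval 31% to 37.3%, which treats genes as independent), against 46.3% of all genes, which argues against it as the main source. The largest rises nevertheless include several such genes, as DEFA5, at a mean log2 level of 6.14 in untreated, 4.54 in scrambled and 6.52 in HAS3 siRNA cells. CYTL1, HBE1, SUGCT and CPE were others, and so were RASD1, GASK1B and CALB1 among the largest falls. LPAR1, SERPINA1 and DDIT4 were among those that went the other way. Of 27 interferon-stimulated genes 4 rose and 2 fell (7 and 2 adjusted over the list alone), so that 14.8% rose (exact 95% interval 4.19% to 33.7%). The share of smaller rises missed in these data was not measured, so an interferon response to the siRNA stays open. Swapped samples would have given a higher HAS3, and it was -0.43 (interval before adjustment -0.80 to -0.07), which argues against a swap, although the value is -0.27 without the second HAS3 siRNA array or the first scrambled array and HAS3 did not pass. An effect of lower HAS3 and an off-target effect of the siRNA sequence both remain, and 1 siRNA cannot separate them.

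The difference between the control groups was weighed last. It comprised 2118 genes, and transfection cannot be told apart from a separate day or batch, because no batch is given for any sample. For the lower ATF4 targets, variation between arrays of 1 group was examined: the replicate arrays differed in the median of this list by at most 0.58 on the log2 scale, in the scrambled group, against a shift of -0.74 between the control groups, which leaves this explanation open.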

How the results depend on the processing

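Among the values that answer a comparison, 356 of those recomputed stayed on their side and within bounds, 51 became weaker, 12 stronger and 2 moved; among single genes and lists 11064 stayed, 488 became weaker, 197 stronger and 1 reversed. In the results that changed the cause was not tested, except where fewer arrays or a stricter threshold lower counts by construction. HAS3 passed under no setting. With 2 arrays per group small changes can be missed, and signal near background limits dim probes: the 2 other background settings compress their changes, for some named genes by more than 1.5 times. A block by slide was not run, as no slide was given. The lone array left in a group was assumed to vary like the other groups.

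With median centring the counts were 1548 lower with Y15; 164 higher and 298 lower with HAS3 siRNA; 551 lower in scrambled than untreated cells; and 994 higher and 2246 lower for the difference of effects. There 33 genes were higher in both, 81 lower in both and 48 lower with Y15 and higher with HAS3 siRNA, r was -0.104 and rho -0.147, 2 lists fell with Y15, and ACTA2, undetected on the Y15 arrays and at least 1.2-fold lower there as reported, was fitted at 0.04 (adjusted p = 0.912). Lists that fell with HAS3 siRNA numbered 5 with cyclic loess. Lists that fell with Y15 numbered 2 with no detection filter and 2 with all probes, lists that rose with Y15 numbered 5 when detection was required on all 8 arrays, and 1 list rose with HAS3 siRNA with all probes. The 4 arrays alone gave 651 genes higher with HAS3 siRNA. At adjusted p under 0.05 and 1.5-fold, 612 were higher in scrambled than untreated cells, 35 higher in both, 121 lower in both, 65 higher with Y15 and lower with HAS3 siRNA, and 80 the reverse. With an estimated correlation 0 lists rose and 0 fell in either comparison, and fry gave 19 up and 6 down with Y15 and 2 up and 1 down with HAS3 siRNA.

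The labels give the arrays replicate numbers and no shared day or batch behind them. With the number as a block within each experiment, 2288 genes were higher and 2732 lower with Y15, 526 and 672 with HAS3 siRNA, 114 higher in both and 159 higher with Y15 and lower with HAS3 siRNA; with a block over all groups 100 were higher in both. As a check of the pairing, replicate differences correlated across genes at 0.274 between untreated and Y15 and 0.042 between scrambled and HAS3 siRNA, and at -0.072 to 0.218 between the other pairs of groups, of which untreated with HAS3 siRNA (0.218) and Y15 with HAS3 siRNA (0.131) were over 0.1.

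Leaving out each array in turn gave 1481 to 2043 genes higher and 1981 to 2356 lower with Y15, 153 to 532 higher and 164 to 681 lower with HAS3 siRNA, 278 to 1259 higher and 418 to 1440 lower in scrambled than untreated cells, and 1223 to 1933 higher and 1009 to 1675 lower for the difference. Genes higher in both numbered 22 to 93, lower in both 70 to 231, higher with Y15 and lower with HAS3 siRNA 39 to 139, and the reverse 55 to 169. Lists up and down numbered 8 to 11 and 1 to 2 with Y15, and 2 to 3 and 3 to 4 with HAS3 siRNA. HAS3 ranged from -0.60 to -0.27. The planned fit without the dim second Y15 array gave 1753 higher and 2228 lower; the share of calls it kept, 79.2%, was computed only after seeing the data.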

Other observations

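The comparison of HAS3 siRNA with untreated cells was chosen only after the results were seen. Epithelial junction genes went both ways with Y15. Of 27 junction and keratin genes 10 fell and 6 rose, also adjusted over the list alone (camera adjusted p = 0.661), with the tight junction genes CLDN7 and CLDN3 down 4.02-fold and 2.54-fold and LAMB3, a laminin chain, up 3.33-fold. Of 32 autophagy and lysosome genes 10 rose and 4 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.264), including the cholesterol transporter NPC1 (3.61-fold) and ATG16L1, which helps form autophagosomes (3.18-fold). Among 37 hypoxia and glycolysis genes 9 rose and 4 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0649), with the peptide hormone gene ADM up 4.86-fold and NDRG1 up 2.94-fold. Of 33 apoptosis regulators 8 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.222). The survival gene MCL1 rose 4.92-fold (log2 fold change 2.30, against 0.87 by a second probe, which also passed), its pro-apoptotic partner BAK1 rose 2.79-fold, and the death-receptor adaptor TRADD fell 2.64-fold. Markers of other cell types also went both ways. Of 7 leukocyte markers 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.394), the macrophage marker CD68 rising 3.47-fold and LAPTM5 falling at least 1.55-fold, a call lost with median centring. Of 7 fibroblast and stromal markers 3 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.222).

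After HAS3 siRNA 4 of 27 interferon-stimulated genes rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.278), with the antiviral gene MX2 up 3.03-fold. MX1 rose 1.89-fold, and its log2 fold change was 0.54 without the second HAS3 siRNA array, with the call lost (adjusted p = 0.127). The stress cytokine gene GDF15 fell 4.32-fold, although the scrambled arrays differed, at 10.45 and 11.57 on the log2 scale. Set against untreated cells, HAS3 siRNA arrays had 1323 genes higher and 1520 lower. In that comparison 36 of 41 ATF4 targets were lower and none higher, at a median of -1.33, and 14 of 17 cholesterol synthesis genes were higher and none lower. CYTL1 stood 2.15 ± 0.13 (SE) and LPAR1 2.59 ± 0.14 above untreated cells on the log2 scale, CPE and RASD1 stood at -1.10 ± 0.15 and -1.54 ± 0.24, and FGFBP1 at 1.83 ± 0.15, each past the threshold (limma adjusted p of 0.000787 or less).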
